A study of Rattus norvegicus with 2 samples.

How the data were processed

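Genomic DNA from liver was compared on 2-colour oligonucleotide arrays for comparative genomic hybridisation, 1 array with male and 1 with female DNA. Per the labels, Sprague-Dawley DNA was labelled with Cy5 and Hirosaki hairless DNA with Cy3 on both arrays, and the dyes were not swapped. Spots were quantified with Agilent Feature Extraction 10.1.1.1 under its CGH protocol, per the file headers. Spot and background intensities in both channels were deposited, and the processed intensities are background-subtracted, spatially detrended and scaled by a linear dye factor, per the file headers. Those factors were 22.1 for Cy3 and 10.5 for Cy5 on the male array, and 16.7 and 11.3 on the female array, so weak Cy3 signals were multiplied more than Cy5 signals. The deposited log10 ratio of red over green was set against the processed intensities and equalled their log ratio within 0.01 on the log2 scale at 99.9% of male and 99.3% of female spots. The series value table holds the same log10 ratios as deposited by the authors, within 0.005, with column medians of -0.00403 for the male and 0.00 for the female array; no part of its scale, direction or centring stayed unknown after this comparison. A p-value of the log ratio per spot, deposited by the authors, was not used. Probe positions were those of the rn4 build (release 3.4), per the file headers. No sequence from the Y chromosome was among the probes (0 probes).

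From the 237974 non-control spots of each array, 123 on the male and 296 on the female array that carried an outlier flag were left out, and replicate spots of a probe were averaged. The SD between spots of a probe was 0.13 log2 on both arrays. No spot was saturated (0 on each array). In Cy3 92.5% of male and 95.6% of female probe spots were well above background, and in Cy5 99.5% and 99.0%. The median background-subtracted signal was 12.7 times the SD of the negative controls in male Cy3 and 37.8 times in male Cy5, against 9.48 and 14.9 on the female array. Among probes dim in both channels, the median log2 ratio was -1.18 over 856 probes on the male array and -0.49 over 1785 on the female array.

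The log2 ratio of the processed Cy5 over Cy3 intensities was centred on the median of the autosomal probes of each array, with no loess or quantile step. The 231339 male and 231170 female probes on chromosomes 1 to 20 and X were put in order, and probes on unplaced sequence were kept apart. Each chromosome was divided by recursive circular binary segmentation written for this work, with a split kept at a t statistic of at least 6 against the noise from differences of neighbouring probes. A region was called where at least 3 neighbouring probes had a mean of at least 0.5 either way and a score, mean times the square root of the number of probes over the noise, of at least 6. Regions were taken as shared where they ran in the same direction and overlapped by at least 50% of the shorter one. Values of shared regions are given over the probes inside called stretches of both arrays, as the mean of the 2 arrays with the SD between them. Each array's own region has at least 3 probes, but the common ones can be fewer, and were 2 in 12 shared regions. Probes between 2 called stretches of a region are left out of its value. The segmentation was tested on simulated data, with regions of known size set into shuffled values of each array. On the male array a shift of 2 over 3 probes was found in 12 of 13 cases (92.3%) and a shift of 1 over 10 probes in 7 of 12 (58.3%). A shift of 1 over 3 probes was found in 0 of 13 cases there, and in 9 of 13 (69.2%) on the female array.

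Probes were tested over both arrays with an intercept in limma 3.58.1 (R 4.3.3), empirical Bayes moderation and Benjamini-Hochberg adjustment over 231160 ordered probes, and called at an adjusted threshold of 0.05 and a mean of at least 0.5 either way. In simulated data for this comparison, also over 231160 probes, 38% of shifts of 1 and 100% of shifts of 2 were called, with 7 calls among unshifted probes. The simulated values were normal and independent between the arrays, with 1 spread per array. Real probes outside shared regions correlated between the arrays (r = 0.51), so these rates need not hold for the real calls. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.

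A probe that was not well above background in a channel on both arrays has only a bound there, given where the other channel was well above background on both. The second condition was added after the data were seen and raised the bound on chromosome 7 from 6.89-fold over 20 probes to 7.31-fold over 19. The bound sets the brighter channel against the higher of the dim probe's own signal and the lowest signal among probes well above background in that channel, per array and then averaged on the log2 scale. Such bounds stay open to dye bias. Bounds between male and female within a channel were set the same way, over probes well above background on 1 array only. A channel is called mostly above background in a region where at least 50% of its probes were so on both arrays, and mostly dim where fewer were so on both.

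The design, the thresholds and the alternatives were fixed before the data were examined. So was the rule for the regions named as shared, which takes at most 20, those with the most probes first. Chosen after the data were seen were the random probe orders, the rule on the median of a region's probes and the 50% rule for dim channels. So were the rule for regions that differ between the male and female arrays and the gap of 1 Mb that joins neighbouring regions. Lists of antigen receptor genes were chosen then too, and nothing is concluded from them. Also chosen then were the counts of short regions by their median, the longest region in random order, the bounds between male and female, and the counts within a channel at equal noise or with signal in an animal. The alternatives were normexp background with an offset of 50, on the median in place of the mean spot signal, centring on the mode, loess within the array, leaving out probes dim in both channels, the series value table, other thresholds of size, score, length and overlap, a segmentation of the mean of both arrays, an intensity trend in limma and each array alone.

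The files pair no probe with a gene, and the gene table used here is on GRCr8, so genes were not placed on rn4. The planned tests of genes and of gene lists were not run for this reason, and the table served only for names, chromosomes and neighbours. A correction for the GC content of the probes was not run, because probe sequences were not used here.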

Results

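Array comparative genomic hybridisation set liver genomic DNA of Sprague-Dawley rats, a widely used laboratory stock, against liver DNA of Hirosaki hairless rats, a strain with a sparse coat that was derived from Sprague-Dawley rats. In this assay the DNA of each strain is labelled with its own dye, and both are hybridised to the same array. The ratio of the dyes at a probe is read as the relative number of copies of that stretch of genome. A sequence variant under a probe can also change its ratio, and this was not tested apart from copy number in any region, short or long. There were 2 arrays, 1 with a pair of male DNAs and 1 with a pair of female DNAs. On both arrays Sprague-Dawley DNA was labelled with Cy5 and Hirosaki hairless DNA with Cy3, so dye and strain cannot be told apart, and each sex rests on 1 array. Each array held 235974 distinct probes with a median length of 60 bp and a median spacing of 7.98 kb, placed on the rn4 build of the rat genome. All ratios are log2 of Cy5 over Cy3, centred on the autosomal median of their array.

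The noise of a single probe, estimated from differences between neighbouring probes, was 0.50 on the log2 scale on the male array and 0.25 on the female array. This estimate also holds ratios particular to a probe, and the SD between spots of a probe was 0.13 on both arrays. The number of arrays limits the precision of every value over both. Cy3 was the dimmer channel, with a median background-subtracted signal of 46.1 on the male and 58.5 on the female array, against 98.0 and 86.4 in Cy5. Across the 231160 ordered probes measured on both arrays the log2 ratios had a Pearson r of 0.56 and a Spearman rho of 0.53, a relation across probes, which are not independent replicates.

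The X chromosome matched the sex given for each animal. The male over female values of each channel were centred on their autosomal median, which puts the autosomes at 0.00 by construction. Relative to this, the median log2 value on the 11298 X probes was -0.92 in the Cy5 channel and -0.91 in the Cy3 channel. The Cy5 over Cy3 ratio on the X chromosome had a median of -0.03 on the male array and 0.00 on the female array. This check speaks to sex alone and carries no information on which strain was in which channel.

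The first question was which parts of the genome differ in copy number between the strains in both sexes. On chromosome 7, from 140184284 to 140259552, 25 neighbouring probes over 75.3 kb had a mean log2 ratio of -4.64 on the male array and -3.71 on the female array, a mean of -4.18 ± 0.66 (SD, n = 2 arrays). The DNA labelled Sprague-Dawley was the one with almost no signal. Of the 25 probes, 4 were well above background in Cy5 on the male array and 5 on the female array, against 24 and 25 in Cy3. Over the 19 probes that were dim in Cy5 and well above background in Cy3 on both arrays, the DNA labelled Hirosaki hairless was at least 7.31-fold brighter. This and all other bounds hold for the processed signals only, and the ratios under normexp are smaller. Under normexp the mean of the region was -0.77, with -0.44 on the male and -1.11 on the female array.

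This direction is opposite to what has been reported for the strain if the region is the known one. The hairless phenotype of Hirosaki hairless rats has been ascribed to a deletion of type II (basic) hair keratin genes, which encode structural proteins of the hair shaft, on chromosome 7, and such a deletion would raise the ratio of Sprague-Dawley over Hirosaki hairless DNA. In the gene table used here, built on the assembly GRCr8, all 6 listed type II hair keratin genes lie on chromosome 7, in the neighbourhood order Krt81, Krt86, Krt83, Krt85, Krt84 and Krt82. The positions of that assembly cannot be set against rn4, so whether the chromosome 7 region holds these genes was not tested. Directions are therefore given by channel throughout, and if the dyes were exchanged on both arrays every direction would turn.

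**Figure D1:**
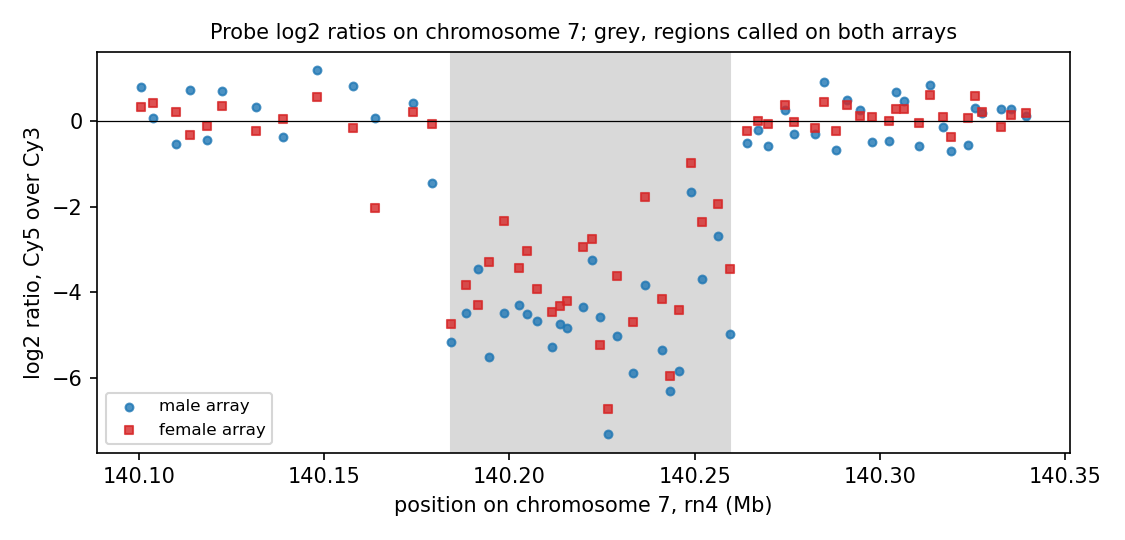
Log2 ratio of Cy5 over Cy3 (vertical axis) of each probe against its position on chromosome 7 in Mb of rn4 (horizontal axis), blue circles for the male array and red squares for the female array, with the region called on both arrays in grey. The 25 probes inside the region averaged -4.64 on the male and -3.71 on the female array, while most of the probes on either side lay near 0.

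The distal part of chromosome 4 held 4 regions within 1056 kb, 2 lower and 2 higher in Cy5. From 167256365 to 167311500, 6 probes had a mean log2 ratio of -4.70 ± 0.56 (SD, n = 2), or -0.77 under normexp. All 6 were dim in Cy5 on both arrays, and over the 5 that were well above background in Cy3 there, Cy3 was at least 10-fold brighter. From 167510178 to 167579436, 7 probes were higher in Cy5, by 3.32 on the male and 1.09 on the female array (2.20 ± 1.58), with 3 of the 7 dim in Cy3 on both arrays and Cy5 at least 2.65-fold brighter there. From 167646058 to 167769236, 12 of the 15 probes lay in called stretches of both arrays and were higher by 1.72 ± 0.06 (1.39 ± 0.20 over all 15), with 6 of them dim in Cy3 on both arrays and Cy5 at least 2.57-fold brighter at these. From 167959464 to 168312318, 38 of the 41 probes lay in called stretches of both arrays and were lower, at -3.31 ± 0.47 (-3.15 ± 0.46 over all 41), or -0.54 under normexp. Over 19 of the 38 that were dim in Cy5 and well above background in Cy3 on both arrays, Cy3 was at least 6.23-fold brighter. Within this last region single probes ranged widely, with an SD between probes of 1.63 on the male and 1.60 on the female array.

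**Figure D2:**
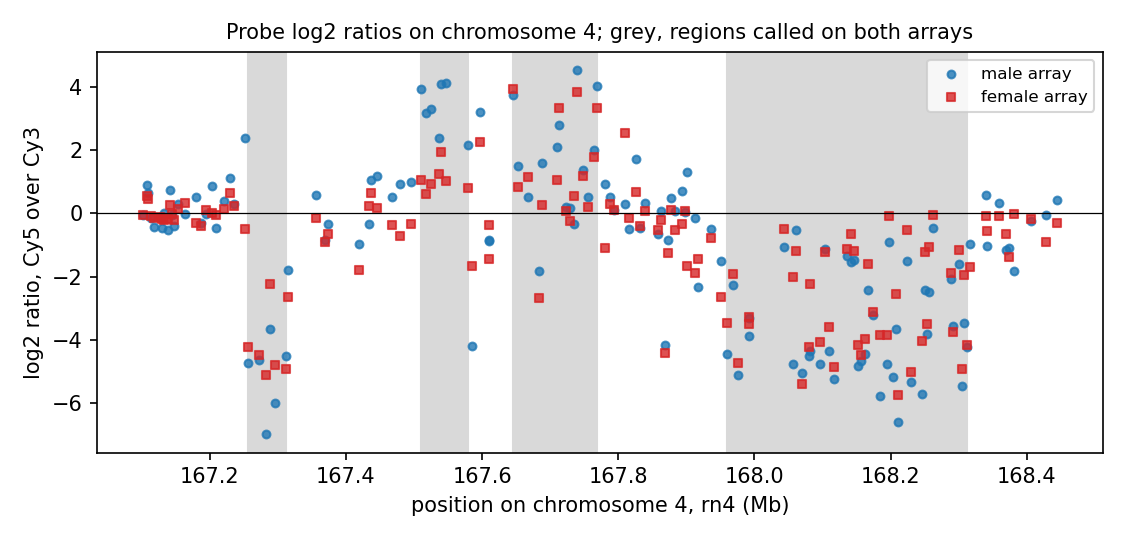
Log2 ratio of Cy5 over Cy3 (vertical axis) of each probe against its position on chromosome 4 in Mb of rn4 (horizontal axis), blue circles for the male array and red squares for the female array, with the 4 regions called on both arrays in grey. Regions lower in Cy5 (means of -4.70 and -3.31) lie on either side of 2 regions higher in Cy5 (means of 2.20 and 1.72).

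Chromosome 6 held 3 of the named regions. From 138913066 to 139863071, 45 probes over 950.0 kb were lower in Cy5, with a mean of -2.68 ± 0.26 (SD, n = 2), or -1.31 under normexp. Over the 8 that were dim in Cy5 and well above background in Cy3 on both arrays, Cy3 was at least 10-fold brighter. The Cy3 signal of the 45 was high, with a median at percentile 99.2 of all probes on the male array and 99.4 on the female array. Further along, 9 probes from 140091677 to 140176485 were higher in Cy5 by 2.33 ± 0.23, with Cy5 at least 2.37-fold brighter over the 4 that were dim in Cy3 on both arrays. Another 6 probes from 140846246 to 140875450 were lower, at -4.42 ± 0.22, or -0.58 under normexp. All 6 were dim in Cy5 and well above background in Cy3 on both arrays, with Cy3 at least 6.19-fold brighter.

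The longest regions higher in Cy5 lay on chromosomes 1 and 15. On chromosome 1, 57 probes from 74482626 to 76069783 were higher by 1.30 ± 0.13 (SD, n = 2), or 0.74 under normexp, with Cy5 well above background at all 57 on both arrays and Cy3 at 49 on the male and 52 on the female array. Over the 5 that were dim in Cy3 on both arrays Cy5 was brighter by at least 1.77 log2. On chromosome 15, 44 probes over 2394 kb, from 28732557 to 31126695, were higher by 2.05 ± 0.27, or 1.00 under normexp. Cy3 was well above background at 25 of these on the male and 32 on the female array, and over the 12 that were dim in Cy3 on both arrays Cy5 was at least 3.47-fold brighter. Elsewhere on chromosome 1, 11 probes from 73502673 to 73606466 were higher by 2.52 ± 0.05, with Cy5 at least 2.01-fold brighter over the 9 that were dim in Cy3 on both arrays, and 8 probes from 61523294 to 61660960 were lower, at -2.78 ± 0.24 (-0.52 under normexp), with Cy3 at least 5.58-fold brighter over the 3 that were dim in Cy5 and well above background in Cy3 on both.

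On chromosome 20, which in the GRCr8 table carries all 67 listed RT1 genes of the rat major histocompatibility complex, 8 probes from 2842685 to 2886964 were higher in Cy5 by 1.75 ± 0.13 (SD, n = 2), or 0.60 under normexp, with 2 of them dim in Cy3 on both arrays and Cy5 at least 3.62-fold brighter there, and 9 of the 12 probes from 4671492 to 4729007, those in called stretches of both arrays, were lower, at -1.77 ± 0.64 (-1.42 ± 0.48 over all 12, and -0.56 under normexp), with 1 of the 9 dim in Cy5 on both arrays. Whether these probes lie in RT1 genes was not tested. On chromosome 17, 10 probes from 72111961 to 72512355 were higher by 2.02 ± 0.31 (1.47 under normexp), with 1 of them dim in Cy3 on both arrays. On chromosome 12, 13 probes from 18231219 to 19388786 were lower, at -1.51 ± 0.06 (-0.67 under normexp), with 1 of them dim in Cy5 on both arrays. Chromosome 3 had 6 probes from 155299067 to 155350198 that were higher by 3.14 ± 0.26 (0.55 under normexp), with 5 of them dim in Cy3 on both arrays and Cy5 at least 3.88-fold brighter there, and 9 probes from 72476488 to 72531676 that were lower, at -1.91 ± 0.68. Of these 9, 4 were dim in Cy5 on both arrays, and only 1 of the 4 was well above background in Cy3 on both, so no fold is given. On chromosome 13, 7 probes from 25953386 to 26085131 were higher by 1.08 ± 0.31, with 2 of them dim in Cy3 on both arrays, but their median did not pass 0.5 on both arrays. On chromosome 2, 23 probes from 86938283 to 87482505 had a mean of -1.06 ± 0.36 with most of them dim in both channels, so no fold is given there. Without the probes dim in both channels its mean was -0.45, short of the 0.5 that a call needs.

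In all, 104 regions were called on both arrays in the same direction, 77 lower and 27 higher in Cy5. Without probes dim in both channels the count was 95, with 68 lower and 27 higher. The 104 regions spanned 11.3 Mb with 624 probes inside. This length runs from the first to the last probe of each region and includes gaps without probes. Short regions made up most of them, with 73 of fewer than 5 common probes, 12 of which had only 2, and 31 of 5 or more. Among the 31 longer ones 20 were lower and 11 higher in Cy5. In 10 of the 31, all lower in Cy5, the Cy5 probes were mostly dim while Cy3 was well above background. In 2, both higher in Cy5, the Cy3 probes were mostly dim. In 8 regions that were lower and 6 that were higher, both channels were mostly well above background. A control with the probes put in the same random order on both arrays gave 83.9 ± 5.67 shared regions of fewer than 5 probes (SD over 10 random orders) and 1.00 ± 1.05 of 5 or more, so the number of short regions was not above what unordered probes gave, and the number of longer ones was. Of the 61 regions of 3 or 4 probes, 39 also had a median past 0.5 on both arrays, more than the 12 ± 4.99 in random order (at most 19). The median of 2 probes equals their mean, so regions of 2 probes are left out of that count. Regions of fewer than 5 probes whose median did not pass 0.5 on both arrays were 22, against 51.9 ± 6.4 in random order. The random orders also scatter the shifted probes of the longer regions, which can add short calls. The totals of short regions therefore do not show that the short regions match unordered probes. With background corrected by normexp the calls fell to 32, and their split turned to 10 lower and 22 higher, and the mean ratio of each of the 20 named regions came closer to 0, with 13 still past 0.5 either way. The 7 that fell short were on chromosome 1 from 73502673 (0.29), chromosome 2 (-0.19), chromosome 3 from 72476488 (-0.34), chromosome 4 from 167510178 (0.38) and from 167646058 (0.31), chromosome 6 from 140091677 (0.43) and chromosome 13 (0.24). This setting changed the background method, the offset and the signal column together. Its offset narrows ratios, so 0.5 is a stricter threshold under it than in the main setting.

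**Figure D3:**
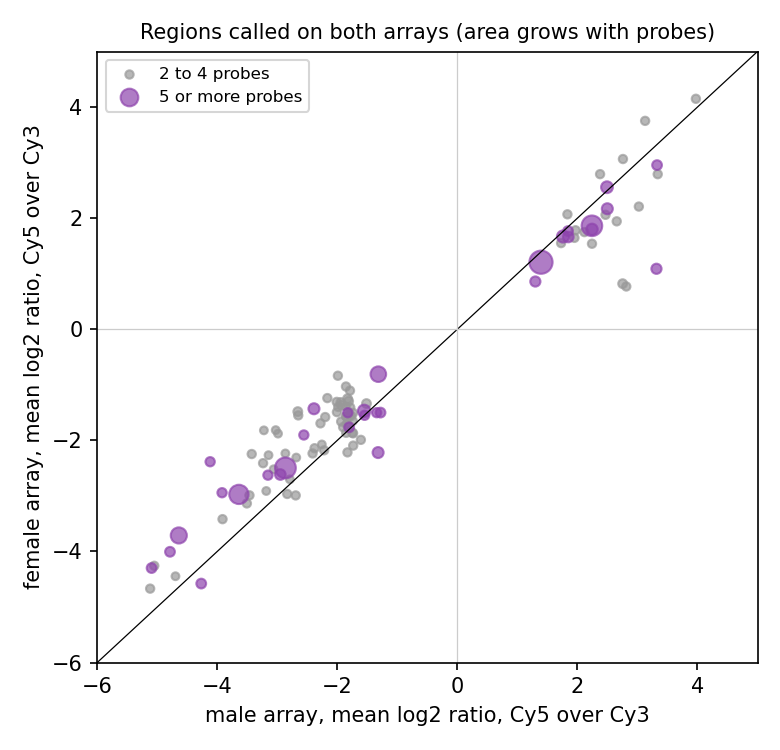
Mean log2 ratio of Cy5 over Cy3 of each of the 104 regions called on both arrays, on the male array (horizontal axis) and on the female array (vertical axis), grey for 2 to 4 probes and purple for 5 or more, with the area growing with the number of probes and the diagonal marking equal values. Of the regions, 77 lie in the lower left and 27 in the upper right.

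**Figure D4:**
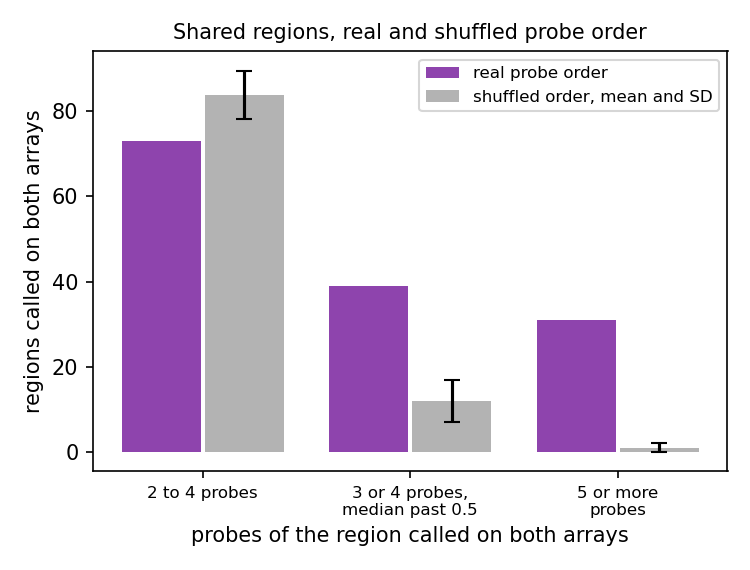
Number of regions called on both arrays (vertical axis) by the number of their probes and, for short ones, their median (horizontal axis), purple bars for the real probe order and grey bars for the mean of 10 random orders with its SD as the error bar. The real order gave 73 regions of 2 to 4 probes, against 83.9 in random order, 39 of 3 or 4 probes with a median past 0.5 on both arrays, against 12, and 31 of 5 or more probes, against 1.00.

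The series names the male and the female comparison as separate analyses, and each array also gave its own list. On the male array 141 regions were called, 98 lower and 43 higher in Cy5, and 45 of them had 5 or more probes. On the female array 423 regions were called, 267 lower and 156 higher, and 82 had 5 or more probes. With the probes in random order the arrays gave 126 ± 6.68 and 532 ± 5.88 regions of any length (SD over 10 random orders), but only 4.40 ± 1.90 and 19.0 ± 5.01 of 5 or more probes. With normexp background the male array called 13 lower and 187 higher, and the female array 53 and 51, so the split by direction was not the same under that setting.

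Of the female array's regions, 301 were not called on the male array, where 282 of these had the same sign and 239 the same sign with a mean past 0.5. Of the male array's, 21 were not called on the female array, where 19 had the same sign but only 6 also a mean past 0.5. These counts were not set against chance, and probes outside shared regions also correlated between the arrays (r = 0.51). The male array, with its larger spread between neighbouring probes, could not have shown most small changes. In simulated data a shift of 1 over 5 probes was found in 2 of 13 cases (15.4%) on the male array. On the female array it was found in 13 of 13 (100%). A shift of 2 over 5 probes was found in 100% of 13 cases on each array.

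The next question was where the male and the female array differed. With 1 array per sex these differences have no replicate check. In all of these regions sex cannot be told apart from the array or from the DNA used. A rule set after the values were seen, at least 5 probes and a difference of at least 1.5 between the arrays, picked 6 regions. On chromosome 5, from 134044135 to 134592966, 47 probes were higher in Cy5 on the male array, at 2.19, and lower on the female array, at -1.09. Over the 45 that were well above background in Cy5 on the male array only, the male Cy5 signal was at least 2.80-fold that of the female. Both ratios rest on dim signals and are not exact. Cy3 was well above background at 1 of the 47 on the male and 5 on the female array, and female Cy5 at 2. On chromosome 10, 5 probes from 44266073 to 44289184 were at 0.02 on the male and -5.12 on the female array, and the Cy5 channel alone differed by 5.21 between the arrays. None of these 5 was well above background in Cy5 on the female array (0 of 5), while all 5 were on the male array, so the male signal was at least 8.17-fold brighter and the log2 values are not exact. On chromosome 1, 8 probes from 107777923 to 107866052 were at -0.94 and -4.60, again with the difference in Cy5, of 3.57, but 0 of the 8 were well above background in female Cy5, which leaves a bound of at least 3.46-fold. On chromosome 20, 5 probes from 803386 to 826867 were at 2.17 and -0.22, with a Cy5 difference of 2.40. There Cy3 was well above background at 1 of the 5 on each array and female Cy5 at 2, so both ratios rest on dim signals, and over 3 probes male Cy5 was at least 4.22-fold brighter.

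The 7 probes on chromosome 4 from 167510178 to 167579436 were at 3.32 and 1.09, with a male minus female difference of -2.15 in Cy3 and 0.09 in Cy5. In male Cy3 0 of the 7 were well above background, and over the 4 that were so in female Cy3 the female was at least 2.28-fold brighter. Also on chromosome 4, 5 probes from 101435725 to 101526370 were lower in Cy5 on both arrays, at -4.12 and -2.38. There the male minus female difference was 0.62 in Cy3. In Cy5 1 of the 5 probes was well above background on each array, so the -1.10 there sets near-background signals against each other.

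**Figure D5:**
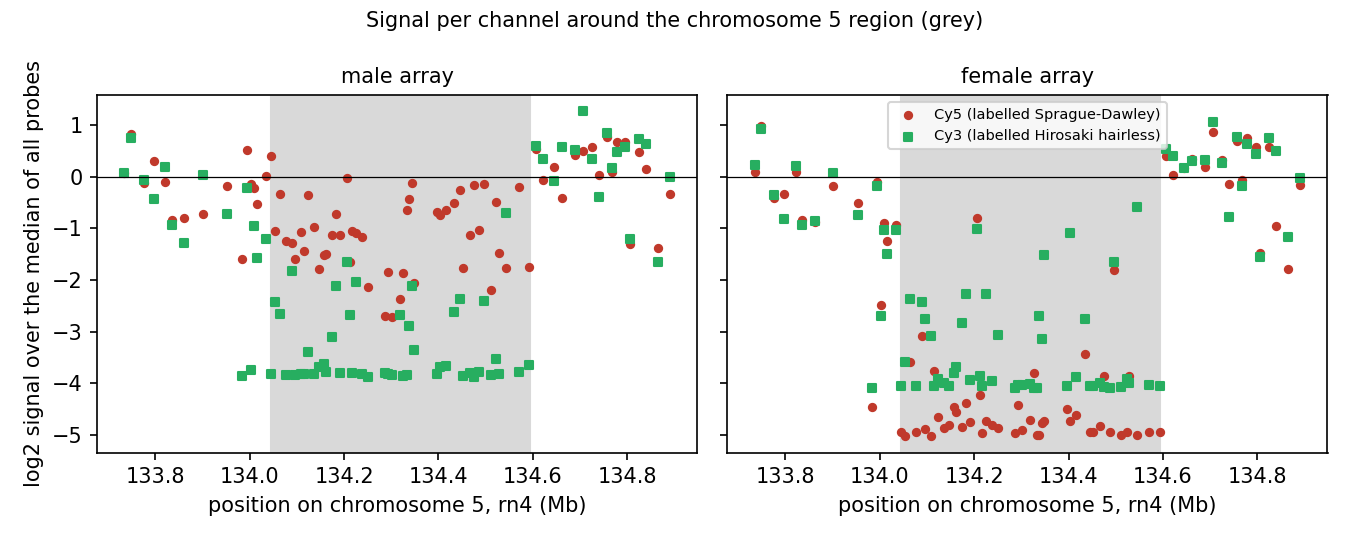
Signal of each probe in log2 over the median of all probes of its channel (vertical axis) against position on chromosome 5 in Mb of rn4 (horizontal axis), for the male array and the female array, Cy5 in red and Cy3 in green, with the region in grey. In the male Cy5 channel all 47 probes were well above background, against 2 in female Cy5, 1 in male Cy3 and 5 in female Cy3.

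Taking both arrays as replicates of the strain comparison, limma's moderated test called 7376 of 231160 ordered probes at a Benjamini-Hochberg adjusted threshold of 0.05, 2376 lower and 5000 higher in Cy5. The smallest mean among them was 0.74 either way. The split was 3672 lower and 4505 higher after loess within each array, and 512 and 2143 under the normexp setting. Without a correction for multiple tests 45882 probes passed 0.05. Since the dyes were not swapped, a probe that takes up the dyes unequally would give such a ratio on both arrays. The labels do not say how many animals each DNA came from, so these tests measure only the spread between the 2 arrays. That spread is mostly pooled over all probes, with 14.6 prior degrees of freedom, and is little informed by a probe's own values.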

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

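The tests of array noise and of near-background signal for the chromosome 5 region were chosen after the result was seen, and the noise test replaced an earlier one that could not have failed.

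On chromosome 5, 47 probes from 134044135 to 134592966 ran in opposite directions, at 2.19 on the male and -1.09 on the female array, a male minus female difference of 3.28 that was not tested, since each sex has 1 array. Noise that is independent between probes is argued against by the random orders, in which no region of either array had more than 26 probes, but this says nothing of noise shared by neighbours. The difference was seen in Cy5, with a male minus female value of 3.33 against 0.04 in Cy3. The 3.33 is inexact, since only 2 of the 47 probes were well above background in female Cy5. Over 45 probes male Cy5 was at least 2.80-fold brighter. In Cy3 1 of the 47 was well above background on the male and 5 on the female array. The 0.04 therefore sets near-background signals against each other and cannot show that Cy3 did not differ. The female array's negative ratio also sets 2 near-background signals against each other and may say nothing of copy number. Male Cy5 was itself low at these probes, with a median signal at percentile 8.89 of all probes. A candidate explanation is that this stretch was present in the male DNA labelled Sprague-Dawley and largely missing from the other 3 DNAs. Whether this goes with sex or with single animals stays open and was not tested, as does a mislabelled DNA.

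On chromosome 20, 3 probes from 246823 to 263190 also ran in opposite directions, at 2.99 on the male and -0.87 on the female array, a difference of 3.86 that was not tested. None of the 3 was well above background in either female channel or in male Cy3 (0 of 3 in each), so -0.87 is a ratio of dim signals, and male Cy5 was at least 3.47-fold brighter than female Cy5.

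Probes on unplaced sequence were kept out of the ordered analysis, and limma called 58 of the 4622 tested there, 40 lower and 18 higher in Cy5. These are 1.25% of them, against 3.19% of ordered probes. The unplaced probes were fitted and adjusted for multiple tests on their own. The cutoffs therefore differ, and the shares cannot be compared directly.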

How the results depend on the processing

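The rule on the median of a region's probes was chosen after the data were seen, and the other settings before. With normexp on median spot and background signals the female array called 104 regions, both arrays shared 32, and 2655 probes passed. A score of 8 left 61 male, 237 female and 49 shared regions, and a score of 5 gave 247, 659 and 166. With the segmentation itself held to stretches of at least 5 probes, 89 male and 68 shared regions were called. A single segmentation of the mean of both arrays gave 249 regions, which need not be called on each array. The median rule left 227 regions on the female array. A size threshold of 1 left 3714 probes, and an intensity trend in limma gave 17614. Leaving out 1 array, the regions ranged from 141 on the male array alone to 423 on the female array alone, and the probes past the size with no test from 18019 on the female to 73030 on the male array. The cause of the normexp and trend values was not tested. The other counts under these settings, a size of 0.3, mode centring, loess, the dim-probe filter, the value table and the other overlaps stayed within 1.5 times the main count. Of 100 values of the 20 named regions under 5 settings, 100 kept their sign, and 28 moved by more than the SD between the arrays, 20 of them under normexp. The value table holds nearly the same ratios as the main setting, and mode centring only moves all ratios of an array by a constant. Those settings are therefore weak checks. No paired analysis was possible because each array is the only one of its sex and its ratio already pairs the strains. The tests of genes and gene lists, with their alternatives, and the GC correction were not run. The weak Cy3 signal limits what can be seen where Cy5 is the brighter channel, since a dim Cy3 probe gives a bound only.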

Other observations

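The random-order control was added after the first counts of regions were seen, its count by median after that control was seen, and the counts at equal noise and with signal in an animal after the 11 against 3 below, while the tests of exchanged labels and failed spots were set before their results were seen.

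Joined at gaps of at most 1 Mb, 38 of the 104 shared regions fell into 11 clusters and 66 stood alone. The largest clusters by number were 8 regions on chromosome 4 from 99101540 to 103207932, 6 of them lower and 2 higher in Cy5, and 7 regions on chromosome 6 from 138673617 to 143020059, 4 lower and 3 higher. Chromosome 1 held 17.1% of all probes in shared regions against 9.87% of ordered probes, chromosome 4 held 16.8% against 7.34%, and chromosome 6 held 13.0% against 5.48%. Chromosome 15 held 8.01% against 3.77%, nearly all in its single long region. These counts and shares were not set against chance, because probes of a region are not independent.

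The chromosome 7 region was lower in the DNA labelled Sprague-Dawley, while the published deletion of this hairless strain would lower the other channel. Failed spots are argued against, since the median Cy3 signal of its probes lay at percentile 50.3 of all probes or higher on each array. Another candidate explanation is exchanged strain labels, and an inbred hairless strain should then differ less between its male and female in Cy5, though the labels do not say that it is inbred. The count set beforehand, regions of at least 5 probes and 1 log2 between male and female, was 11 in Cy5 against 3 in Cy3 (exact binomial test, two-sided, p = 0.0574), or 8 against 3 with signal in at least 1 animal (p = 0.227), 11 against 2 at equal noise (p = 0.0225) and 8 against 2 with both (p = 0.109), while regions of any kind were 68 against 381, or 68 against 42 at equal noise. Each channel rests on 1 male and 1 female DNA. The p-values therefore treat regions of a single pair as independent and do not measure variation within a strain. The 11 in Cy5 also include a stretch over the chromosome 7 region itself and the chromosome 4 region from 101435725, both mostly dim in Cy5. These counts turn on the choice made and were not corrected for the number of choices, so exchanged and correct labels cannot be told apart here.

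Short shared regions were as frequent without any order of the probes, with 63.9 of 3 or 4 probes on average in random orders against 61 in the real order. This is consistent with single probes that give the same ratio on both arrays, from a sequence variant under the probe or from unequal uptake of the dyes, which were not tested apart, since no dye swap was made. It does not hold for all of them, since 39 of the 61 had a median past 0.5 on both arrays, above the mean of 12 and the largest count of 19 in random order. The random orders also scatter the shifted probes of the longer regions, so the similar totals do not show how many short regions come from single probes. Outside shared regions the arrays correlated across probes (r = 0.51), while neighbouring probes hardly did (r = 0.02).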
